A study of Mus musculus with 6 samples.

How the data were processed

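RNA from 6 B16F10 tumours, 3 from untreated and 3 from vorinostat-treated mice, was measured by total RNA sequencing. Per the labels' protocols, RNA was extracted with a column kit, libraries were made with a stranded total RNA kit and sequenced as paired-end reads of 150 bases on an Illumina NovaSeq instrument. Per the submitters' processing notes, the tools named were FastQC, Trim Galore and Salmon, with GRCm38 as the genome build. Their versions and the annotation used for quantification are not given in the sources used here.

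Each deposited file holds 1 library with 44679 Ensembl genes and, per the file headers, a length, an effective length, a TPM value (abundance scaled for length and library size) and an estimated count of reads for each gene. The estimated counts deposited by the authors are Salmon's and need not be whole, so they were rounded to whole numbers before the count tests. The TPM values deposited by the authors were used only in alternatives. Gene symbols, types and positions came from the GENCODE annotation of GRCm38, in which 44118 of the gene identifiers were found; the other 561 had no symbol and kept their identifier. Reads that Salmon assigned to no gene are not in these files, so shares are of assigned reads.

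The groups were taken from the treatment given in the labels. The replicate numbers follow the order of the samples and pair nothing. The titles also carry numbers after the letters G, N and S, whose meaning is not given in the sources used here. The S numbers are 62, 57 and 63 for untreated tumours 1, 2 and 3 and 58, 59 and 60 for vorinostat tumours 1, 2 and 3. The G numbers are 1, 1 and 2 against 3, 3 and 4, so they never occur in both groups and could not be a covariate beside treatment. A model with tumours of the same G number as related samples was not tried, and the tests treated all tumours as independent.

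The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, filterByExpr by group, dispersions that were not robust, treatment as the only term, two-sided p-values and Benjamini-Hochberg adjustment with a threshold of 0.05. Standard errors of log2 fold changes were derived from the fold change and its F statistic. The filter kept 14776 genes, and the biological coefficient of variation was 0.314. CPM values are counts scaled to a common library size with TMM factors, given as mean ± SD over 3 tumours. A count of 3 reads was taken as the detection limit of a library. Gene lists, 40 with 762 entries, were written before the data were examined, as were the tests, most other settings tried and the rule for naming genes. They were tested with camera (limma 3.58.1, preset correlation 0.01) where 5 or more members were tested, with Benjamini-Hochberg adjustment over the 36 lists tested, and beside it with an estimated correlation and with fry. Members were also adjusted over the list alone.

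The rule for named genes took, because no gene passed the threshold, the 5 genes with the smallest p in each direction, given as values only, from those with a usual symbol, a mean of 1 CPM or more in a group and group ranges that do not overlap. It also took up to 4 called members of each called list, 1 member of every other list by smallest p, and 10 fixed genes. As no list member was called, the 4 members with the smallest p stand in for called ones, a choice made after the values were seen. Ccng1, Trp53inp1 and Gata2 are named in addition, also chosen after their values were seen. For some lists the member so chosen is not reported here.

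The other settings tried for genes were DESeq2-type size factors and upper-quartile scaling in edgeR, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom with and without sample quality weights, robust dispersions, an effective length offset, limma on log2(TPM + 1) and log2(TPM + 0.1), TPM without a filter, mitochondrial and ribosomal RNA left out, a minimum fold of 1.5, and each library left out in turn. For lists these were the estimated correlation, fry, each library left out, and members shared by lists left out. Settings added after the data were examined were protein-coding genes alone, the satellite share as a covariate, untreated tumour 3 and vorinostat tumour 3 both left out, satellite and ribosomal DNA genes left out, and a genomic background, estimated from 1336 chemoreceptor genes, subtracted. The 13 satellite-annotated genes were chosen after the libraries were seen.

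The test was checked on simulated counts for this comparison of 3 against 3, drawn for 14776 genes from the means and library sizes of these samples. The genes to be changed were picked from those with a mean of 1 CPM or more. Of 100 genes changed 2-fold 48% were recovered, and of 100 changed 4-fold 83%, with 11 false calls among 13686 genes tested. A list of 20 genes shifted by 0.8 on the log2 scale was called with the preset and the estimated correlation, and 0 of 35 unshifted lists were called. The genes were drawn independently of each other, so members of a simulated list were not correlated. The simulated tumours also shared no structure across genes. The 0 of 35 therefore does not measure false list calls in these data. Nor do the shares recovered and the call of the shifted list measure what real changes would reach in these tumours. The depth of 2.79 M to 7.35 M nuclear protein-coding reads per library limits the precision of genes near 1 CPM.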

Results

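Total RNA was sequenced from 6 tumours of B16F10, a pigmented mouse melanoma line that grows as a skin tumour in mice. Of these tumours 3 came from untreated mice and 3 from mice given vorinostat, an inhibitor of histone deacetylases, the enzymes that remove acetyl groups from histones and other proteins. The series title sets the work in the tumour microenvironment, so the comparison asks what the drug did to the RNA of the tumour cells and of the host cells among them. Per the labels the RNA came from pellets of tumour cells; whether host cells were sorted out or depleted beforehand is not given in the sources used here, so host cell values describe what remained in the pellets. The labels name the tumours as separate samples but do not say that each came from a different mouse. The p-values therefore measure the spread between these 6 samples. The reads assigned to genes numbered 24.2 M, 11.3 M and 28.9 M in untreated tumours 1, 2 and 3. They numbered 21.9 M, 13.2 M and 13.5 M in vorinostat tumours 1, 2 and 3.

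The libraries differed widely in which RNA filled them. The 2 mitochondrial ribosomal RNAs took 55.9% of the reads of untreated tumour 3 and between 13.3% and 25.3% in the other 5 libraries. Nuclear protein-coding genes took 27.6% ± 16.1 of the reads in untreated tumours and 32.0% ± 11.5 in treated ones (SD, n = 3 each), with 10.3% as the lowest share, in untreated tumour 3. That left 7.35 M, 4.76 M and 2.97 M nuclear protein-coding reads in the untreated tumours and 6.89 M, 5.77 M and 2.79 M in the treated ones. A set of 13 predicted genes whose annotated exons lie in satellite repeats, such as Gm26870 on chromosome 9 from 3000282 to 3038313 (GRCm38), took 22% of the reads of vorinostat tumour 3. The same genes took 0.337%, 9.83% and 0.174% in untreated tumours 1, 2 and 3, and 1.63% and 8.0% in vorinostat tumours 1 and 2. The difference in that share between the groups was within the spread (exact permutation p = 0.5, two-sided, n = 3 each; the smallest p such groups allow is 0.1). Genes with a read numbered 22738, 22856 and 21595 in untreated tumours 1, 2 and 3 and 25810, 24618 and 28510 in vorinostat tumours 1, 2 and 3. Reads in 1336 chemoreceptor genes, which are silent in most tissues, stood at 36.8, 58.5 and 25.3 RPM (reads scaled to library size) in the untreated and at 65.0, 90.1 and 167 RPM in the treated tumours. Neither of these measures overlapped between the groups, a separation that chance gives in 10% of measures. The RPM, unlike the CPM of genes, used all assigned reads and no TMM factors. With these factors untreated tumour 3 had 730 chemoreceptor reads in an effective library of 10.5 M. Vorinostat tumours 1 and 2 had 1423 in 25.3 M and 1190 in 21.8 M. On that scale chemoreceptor reads overlapped between the groups, so their separation rests on the scaling.

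**Figure D1:**
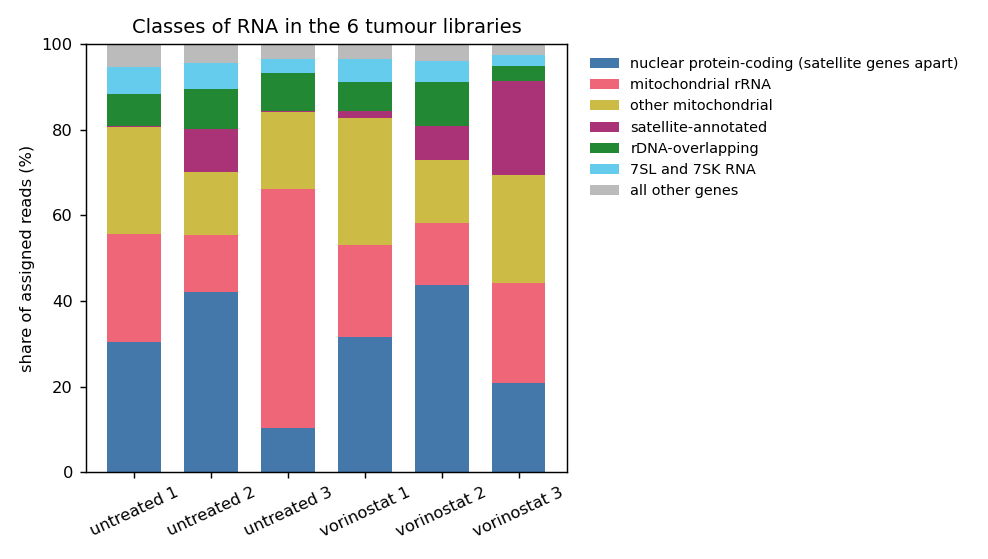
Share of assigned reads (%, vertical axis) taken by 7 classes of gene in each of the 6 tumour libraries (horizontal axis). Mitochondrial ribosomal RNA fills 55.9% of untreated tumour 3, and satellite-annotated genes fill 22% of vorinostat tumour 3.

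The treated and untreated tumours did not separate as groups. The first principal component of log2 CPM (counts scaled to library size) held 52.4% of the variance. It placed untreated tumours 1 and 3 at -59.3 and -60.8, untreated tumour 2 at 19.2, vorinostat tumours 1 and 2 at 8.78 and 3.62, and vorinostat tumour 3 at 88.6. The second component held 20.7% of the variance and set untreated tumour 3 at 53.9 and vorinostat tumour 3 at 32.4, with the other 4 libraries below 0. Untreated tumour 3 and vorinostat tumour 3 are also the tumours that share their G number with no other. Spearman correlations across genes ran from 0.941 to 0.969 among the untreated tumours, from 0.945 to 0.978 among the treated tumours and from 0.921 to 0.975 between the groups.

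The first comparison asked which single genes differed between treated and untreated tumours. Of the named genes, Hmox1, which encodes heme oxygenase 1, had the smallest p among those higher in treated tumours, at 98.4 ± 48.3 CPM against 31.2 ± 4.28 CPM (SD, n = 3 each). Among those lower in treated tumours, the small nucleolar RNAs Snora73b and Snora73a and a copy of the U3 small nucleolar RNA, Rnu3b4, had some of the smallest p. No gene of the 14776 tested passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, and the smallest adjusted p was 0.316. At an unadjusted p under 0.05 there were 927 genes, 496 higher and 431 lower in treated tumours, where 739 would be reached with no effect at all. DESeq2 called 11 genes and limma-voom called 0, or 6 with sample quality weights.

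Hmox1 (ENSMUSG00000005413, chromosome 8 from 75093621 to 75100589, GRCm38) was 3.16-fold higher in treated tumours, a log2 fold change of 1.66 with an SE of 0.31 and an edgeR adjusted p of 0.706. All 3 treated tumours lay above all 3 untreated ones, which the naming rule required. DESeq2 gave Hmox1 an adjusted p of 1.00e-04, and over the settings tried it ran from 3.63e-08 with no filter to 1.0. Ache, which encodes acetylcholinesterase, stood at 6.48 ± 2.44 CPM against 2.29 ± 0.245 CPM, a log2 fold change of 1.47 (SE 0.31, edgeR adjusted p 0.743). It shares its locus with the microRNA gene Mir8116 on the same strand, so part of these reads cannot be assigned with certainty. Gsta4, a glutathione S-transferase that detoxifies products of lipid peroxidation, stood at 13.3 ± 2.76 CPM against 6.88 ± 2.03 CPM (log2 fold change 0.93, SE 0.23, edgeR adjusted p 0.743). Rasgrf1, a nucleotide exchange factor for Ras, had 102 reads over the 3 treated libraries and 10 over the untreated ones, and Unc5cl had 60 and 4. No untreated library held more than 6 reads of either, so no fold is given for them.

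Snora73b (ENSMUSG00000065353, chromosome 4 from 132352322 to 132352526) did not pass the edgeR threshold, at 40.5 ± 8.92 CPM in treated against 166 ± 67.1 CPM in untreated tumours, a log2 fold change of -2.03 (SE 0.30, adjusted p 0.316). Its near copy Snora73a (ENSMUSG00000064387, chromosome 4 from 132352775 to 132352979) stood at 15.4 ± 3.36 against 57.1 ± 26.8 CPM (log2 fold change -1.87, SE 0.32, edgeR adjusted p 0.530). Both lie inside Snhg3 and Rcc1 on the same strand, and their reads can be split between the copies or shared with these hosts. DESeq2 gave Snora73b an adjusted p of 5.87e-09 and Snora73a 2.12e-05, and over the settings tried these ran from 1.29e-11 and 5.14e-13 with no filter to 1.0. Rnu3b4 stood at 90.1 ± 15.2 CPM against 551 ± 396 CPM, but it lies inside Tex14 and is 1 of 4 genes with a U3 symbol between which reads can be shared, and their log2 fold changes ran from -2.61 to 1.63. Summed over the copies, the 4 U3 genes stood at 190 ± 33.8 against 691 ± 430 CPM and the 2 Snora73 genes at 56.0 ± 12.3 against 223 ± 93.7 CPM. In both sums all 3 treated tumours lay below all 3 untreated ones. The naming rule had required such a separation of Rnu3b4, Snora73a and Snora73b themselves, so it is no further support. Untreated tumour 2 lay nearest to the treated tumours, with a U3 sum of 237 CPM against 157 to 225 CPM in these and 746 and 1091 CPM in untreated tumours 1 and 3. Rnu3b4, Snora73a and Snora73b were also called between untreated tumours 1 and 3 and the other 4 libraries. Lifr, the receptor for leukemia inhibitory factor, stood at 15.1 ± 1.01 against 25.3 ± 2.28 CPM (log2 fold change -0.75, SE 0.14, edgeR adjusted p 0.706). Man1a, a mannosidase that trims N-glycans, stood at 8.15 ± 0.474 against 14.1 ± 1.60 CPM (log2 fold change -0.79, SE 0.16, edgeR adjusted p 0.743).

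**Figure D2:**
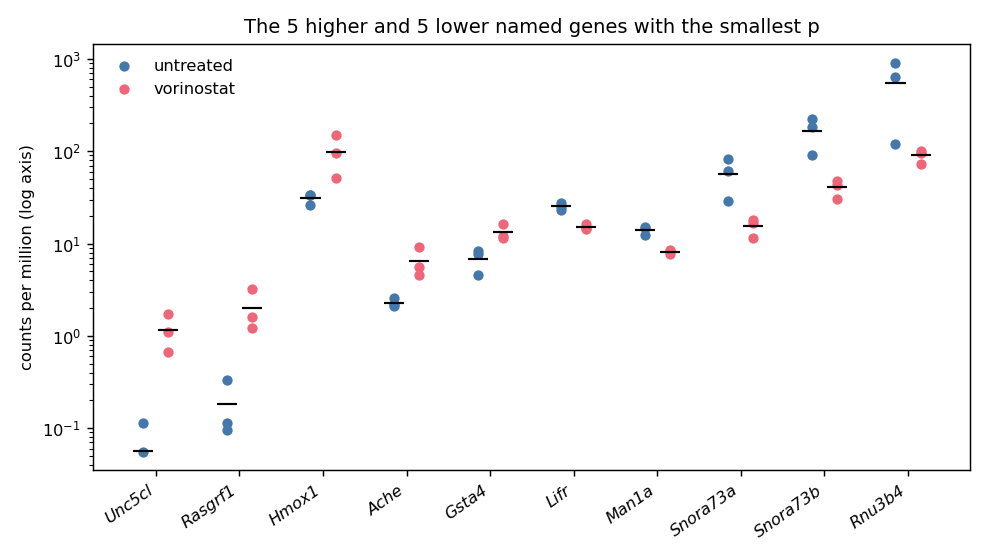
CPM (counts scaled to library size, vertical log axis) of the 5 named genes with the smallest p in each direction, in 3 untreated and 3 vorinostat tumours; points are tumours and lines are group means. Untreated tumour 3 has 0 reads of Unc5cl and so no point for it; none of these genes passed the edgeR adjusted threshold.

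Of the genes fixed in advance as readouts of the drug and of the tumour, none passed the edgeR threshold. Cdkn1a, the cell cycle inhibitor p21 and a known target of histone deacetylase inhibitors, stood at 47.3 ± 5.74 CPM in treated and 46.4 ± 6.59 CPM in untreated tumours. The linker histone gene H1f0 stood at 105 ± 9.51 against 123 ± 14.4 CPM, and Hdac1, which encodes a target of the drug, at 25.8 ± 3.05 against 24.3 ± 4.82 CPM. The melanocyte transcription factor Mitf stood at 206 ± 22.2 against 213 ± 15.8 CPM and the pigment enzyme Tyr at 157 ± 38.0 against 154 ± 13.9 CPM. The light chain of MHC class I, B2m, stood at 134 ± 33.1 against 161 ± 54.9 CPM, and the heavy chain H2-K1 at 60.3 ± 12.7 against 73.4 ± 17.1 CPM. Cd274, which encodes PD-L1, stood at 8.04 ± 1.33 against 9.90 ± 1.92 CPM. The T cell genes Cd8a and Foxp3 stood low, at 1.33 ± 0.336 against 0.862 ± 0.555 CPM and 0.731 ± 0.203 against 1.84 ± 1.25 CPM, where 3 reads correspond to between 0.114 and 0.285 CPM depending on the library. These limits cover counting error only. On log2(TPM + 1), where the median of all genes was 0.26, the log2 fold changes were 0.28 for H1f0, 0.42 for Mitf, 0.29 for B2m, 0.26 for H2-K1 and 0.10 for Cd274.

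The gene-level count of 0 depended on the test, the filter, the input scale and the libraries. It was 39 on log2(TPM + 1) and 52 on log2(TPM + 0.1), both with limma, and satellite-annotated genes made up 13 of each of these counts. Without untreated tumour 2, edgeR called 121 genes, 29 higher and 92 lower in treated tumours, among them Snora73b, Snora73a, Rnu3b4, Hmox1, Lifr and Man1a. Of the 29 higher ones 12 were satellite-annotated. Without untreated tumour 3 edgeR called 1, the pseudogene Ppp1ccb, which was lower in treated tumours. The group ranges did not overlap for 1782 genes, 12.1% of those tested, where chance gives 10%.

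The second comparison asked whether genes of a pathway or cell type differed together. Of 40 lists, 36 had enough members to test, and the camera test with its preset correlation called 7 of them. The neuronal list was higher in treated tumours, and the lists for MHC class II, MHC class I, type I interferon, fibroblasts and matrix, immediate early and heat shock genes, and cell cycle inhibitors with histone deacetylase inhibitor response were lower. On log2(TPM + 1) and log2(TPM + 0.1) the median of all genes was 0.26 and 0.51. Relative to it, all 6 lower lists stayed lower on log2(TPM + 0.1), from -0.61 for MHC class II to -0.13 for immediate early and heat shock genes. On log2(TPM + 1) MHC class II (-0.34), type I interferon (-0.16) and fibroblasts and matrix (-0.17) stayed lower, while MHC class I (0.00), the inhibitor response (0.00) and immediate early and heat shock genes (0.03) did not. The neuronal list stood 0.05 above all genes on log2(TPM + 1) and 0.36 above on log2(TPM + 0.1). None of the 7 held with an estimated correlation, where their adjusted p lay between 0.902 and 0.920. Fry, which asks whether the members of a list move one way, also called 0 lists, with an adjusted p of 0.961 for each of the 7. For p53 targets the estimated correlation was 0.0033, under the preset one. Yet their unadjusted camera p rose from 0.0845 to 0.144 with it. The loss of the 7 calls therefore need not rest on correlated members alone. The preset test called 13 lists without untreated tumour 2 and 11 without vorinostat tumour 2.

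**Figure D3:**
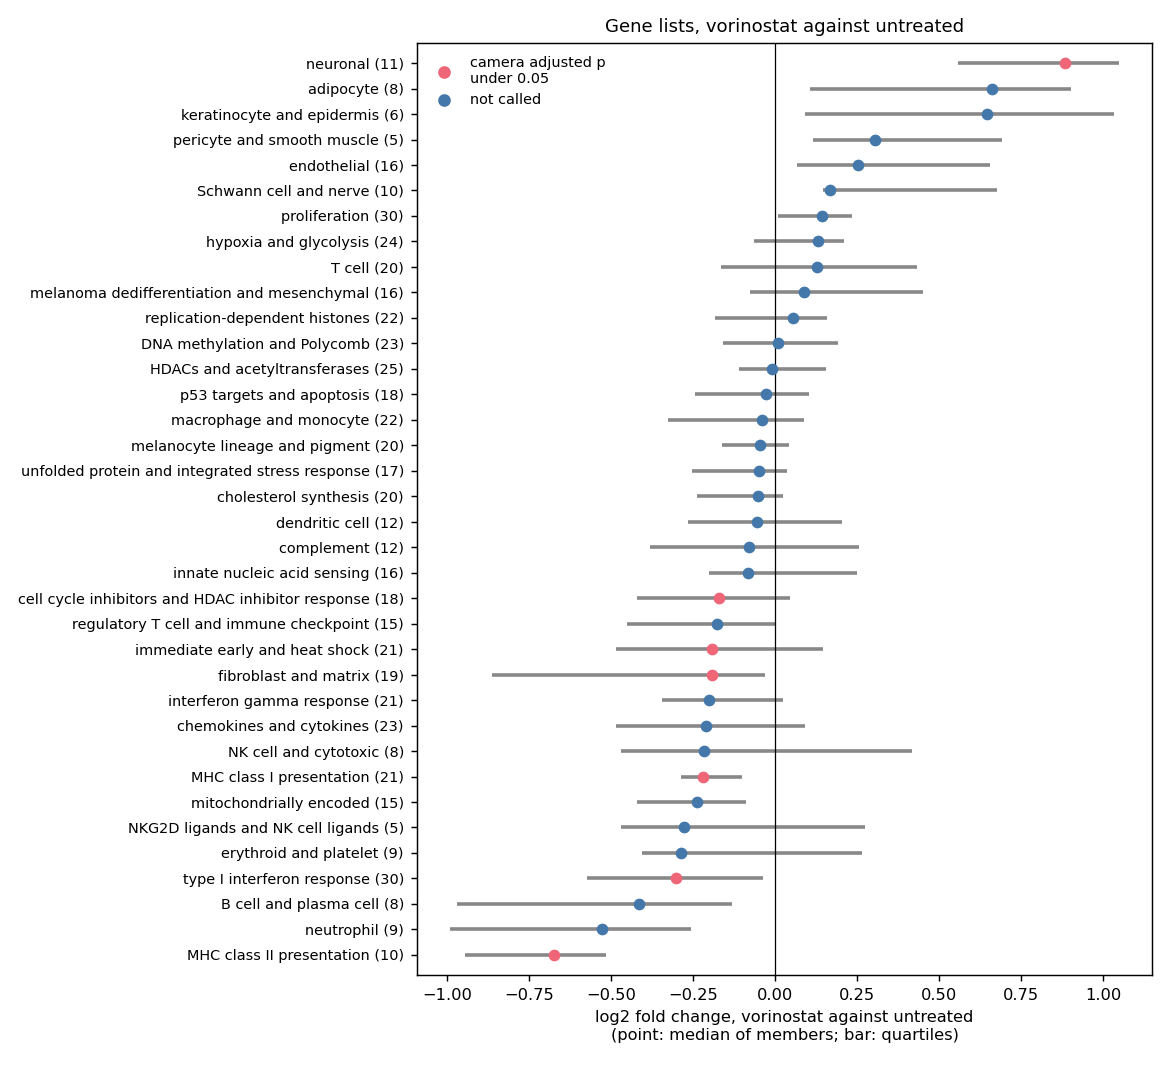
Median log2 fold change (point) and quartiles (bar) of the tested members of 36 gene lists, vorinostat against untreated, n = 3 tumours each; the number of members is in brackets. Medians run from -0.67 for MHC class II to 0.88 for the neuronal list, and all 7 calls (red) lost significance with an estimated correlation, with an adjusted p of 0.902 to 0.920; relative to the median of all genes on log2(TPM + 1), MHC class I, the inhibitor response and immediate early and heat shock genes were not lower.

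Genes of antigen presentation and interferon response were lower in treated tumours as lists in edgeR, though MHC class I was not lower than the median of all genes on log2(TPM + 1). For MHC class II, 9 of 10 members were lower, with a median log2 fold change of -0.67 (camera adjusted p 0.000564, and adjusted p = 0.902 with an estimated correlation). The chains H2-Aa and H2-Eb1 stood at 13.6 ± 4.96 against 27.8 ± 17.3 CPM and at 9.50 ± 2.49 against 19.0 ± 13.0 CPM, H2-Ab1 at 17.8 ± 7.10 against 30.3 ± 17.4 CPM, and the peptide-loading chain H2-DMa at 2.05 ± 0.594 against 4.07 ± 1.83 CPM. Of the type I interferon list, 23 of 30 members were lower with a median of -0.30 (camera adjusted p 0.00293, and adjusted p = 0.902 with an estimated correlation). Its examples were Ifit3 at 4.20 ± 0.481 against 7.19 ± 1.90 CPM, Stat2 at 5.11 ± 1.51 against 7.74 ± 0.565 CPM, Cmpk2 at 5.03 ± 0.725 against 7.12 ± 0.621 CPM and Rsad2 at 11.7 ± 1.19 against 17.5 ± 7.09 CPM. Of the MHC class I list, 18 of 21 members were lower with a median of -0.22 (camera adjusted p 0.00931, and adjusted p = 0.920 with an estimated correlation), among them Tap2, H2-T22, Tapbp and Erap1 with log2 fold changes of -0.35, -0.45, -0.27 and -0.27. No single member of these 3 lists was called over all genes or when adjusted over the list alone. Untreated tumour 3 had the highest level of Ptprc, the pan-leukocyte marker CD45, at 28.3 CPM against 6.69 to 18.2 CPM in the other 5 tumours. Without that tumour the median was -0.24 for MHC class II (camera adjusted p 0.130), -0.22 for type I interferon (0.0968) and -0.22 for MHC class I (0.0810). The MHC class I call was also lost without untreated tumour 1 (median -0.15, 0.184) and without vorinostat tumour 3 (median -0.13, 0.25). The other way, the medians were -1.04 for MHC class II and -0.45 for MHC class I without untreated tumour 2, and -1.08 and -0.34 without vorinostat tumour 1. With the satellite share as a covariate the medians were 0.02 for MHC class II (camera adjusted p 0.835), -0.12 for type I interferon (0.394) and 0.16 for MHC class I (0.320). Without untreated tumour 3 and vorinostat tumour 3 they were -0.16 (0.187), -0.21 (0.187) and -0.08 (0.870).

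Lists of immune cell types were not called. The median was -0.04 over 22 macrophage and monocyte genes (camera adjusted p 0.295), although Arg1 stood at 8.97 ± 1.78 against 17.1 ± 7.50 CPM. Without untreated tumour 3 the macrophage list was called higher, at a median of 0.32 (camera adjusted p 0.00251), and without untreated tumour 2 it was called lower, at -0.38 (3.19e-05). All 9 neutrophil genes tested were lower, with a median of -0.53 (camera adjusted p 0.147) and S100a9 at 1.31 ± 0.781 against 3.82 ± 4.26 CPM. The median was 0.13 for 20 T cell genes (camera adjusted p 0.967; Trbc1 -0.84, SE 0.71) and -0.22 for 8 genes of NK and cytotoxic cells (0.975; Tbx21 1.53, SE 0.75). It was -0.18 for 15 genes of regulatory T cells and checkpoints (0.217), -0.41 for 8 genes of B and plasma cells (0.508; Ighm -1.06, SE 0.46) and -0.05 for 12 dendritic cell genes (0.936; Zbtb46 0.58, SE 0.28). The medians were -0.20 for the interferon gamma response (camera adjusted p 0.295; Nos2 -1.23, SE 0.62), -0.08 for innate nucleic acid sensing (0.668; Irf3 0.37, SE 0.17), -0.21 for chemokines and cytokines (0.306; Cxcl3 -0.86, SE 0.50) and -0.08 for complement (0.936; C1ra 0.37, SE 0.21). Of the ligands of NKG2D and other NK receptors 5 were tested, with a median of -0.28 (0.775; Clec2d -1.48, SE 0.69). Without untreated tumour 2 the camera test also called the neutrophil (median -1.01), regulatory T cell (-0.51), interferon gamma (-0.46) and chemokine (-0.42) lists lower. It called interferon gamma lower without vorinostat tumour 1 (-0.42) and neutrophils lower without vorinostat tumour 3 (-0.92). Without untreated tumour 3 the medians were positive, with no call, for B cells (0.98), NK cells (0.50), complement (0.28), dendritic cells (0.21), regulatory T cells (0.20), chemokines (0.15), neutrophils (0.05), NK cell ligands (0.05) and interferon gamma (0.01). Medians also turned with no call for T cells without untreated tumour 2 (-0.26) or vorinostat tumour 3 (-0.18), and for NK cells without untreated tumour 1 (0.06) or vorinostat tumour 2 (0.17). They turned for B cells without vorinostat tumour 2 (0.15) or over protein-coding genes alone (0.61), for complement without vorinostat tumour 1 (0.03), and for dendritic cells without untreated tumour 1 (0.00) or vorinostat tumour 1 (0.01) or 2 (0.06). With the satellite share as a covariate the T cell (0.48, camera adjusted p 0.0474) and NK cell (0.71, 0.0382) lists were called higher, as were macrophages, interferon gamma, chemokines and complement.

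Neuronal genes were higher in treated tumours as a list with the preset correlation. Of 11 members tested 10 were higher, with a median log2 fold change of 0.88 (camera adjusted p 0.00293, and adjusted p = 0.902 with an estimated correlation). The glycolytic enzyme of neurons Eno2 stood at 13.3 ± 1.89 against 7.77 ± 1.99 CPM and was the 1 member that passed when adjusted over the list alone (0.0352). The ubiquitin hydrolase Uchl1 stood at 7.57 ± 2.15 against 3.91 ± 1.5 CPM, the neurofilament gene Nefh at 2.01 ± 1.91 against 0.883 ± 0.548 CPM (4.22 CPM in vorinostat tumour 3; log2 fold change 0.07 without it) and the tubulin gene Tubb3 at 8.91 ± 1.77 against 6.93 ± 1.90 CPM. The list was called without each library in turn, but its median was 0.28 without vorinostat tumour 3, the library with the most satellite reads, and 0.52 without untreated tumour 1. Without untreated tumour 3 and vorinostat tumour 3 the call was lost (median 0.21, camera adjusted p 0.0510), as it was with the satellite share as a covariate (median 0.30, 0.128). The mean log2 CPM of the list was 1.57 in untreated tumour 2, above 1.31 and 1.18 in vorinostat tumours 1 and 2 and below 2.23 in vorinostat tumour 3. Genes with a read and chemoreceptor reads per assigned read were also higher in all 3 treated tumours than in any untreated one. Scaled with TMM factors, chemoreceptor reads overlapped between the groups.

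Fibroblast and matrix genes were lower as a list, with 15 of 19 members lower at a median of -0.19 (camera adjusted p 0.00409, and adjusted p = 0.902 with an estimated correlation). The collagen gene Col3a1 stood at 1.25 ± 0.235 against 6.52 ± 5.84 CPM, Col1a2 at 2.75 ± 0.606 against 4.95 ± 1.73 CPM, Col1a1 at 3.34 ± 1.70 against 5.96 ± 2.03 CPM and the matrix protein gene Postn at 0.447 ± 0.345 against 1.51 ± 0.909 CPM. Col3a1 reached 12.8 CPM in untreated tumour 3. The list was not called without that tumour (median -0.11, camera adjusted p 0.130) or without vorinostat tumour 1 (-0.20, 0.0564). Its median was -0.30 without untreated tumour 1, -0.44 without untreated tumour 2 and -0.48 without vorinostat tumour 3. Without untreated tumour 3 and vorinostat tumour 3 together the list was called (-0.25, camera adjusted p 0.00369). The call also held with the satellite share as a covariate (-0.19, camera adjusted p 0.0397). Other tissues of the tumour bed were not called. Adipocytes were called higher without untreated tumour 3 (median 0.80, camera adjusted p 0.00251), without it and vorinostat tumour 3 (0.59, 0.00369) and with the satellite share as a covariate (0.55, 0.0332). The medians were 0.25 for endothelial genes (camera adjusted p 0.566; Vwf 0.66, SE 0.27), 0.30 for pericytes and smooth muscle (0.443; Cspg4 0.69, SE 0.42) and 0.65 for keratinocytes and epidermis (0.470; Krt5 1.11, SE 0.92). They were 0.66 for adipocytes (0.235; Plin4, with 49 treated and 11 untreated reads), -0.29 for erythroid cells and platelets (0.936; Ppbp -1.28, SE 0.96, and 0.75 without untreated tumour 3) and 0.17 for Schwann cells and nerve (0.235). Vorinostat tumour 3 carried several of these values: without it the medians were -0.47 for endothelial genes, -0.23 for keratinocytes, 0.15 for adipocytes and 0.00 for pericytes, with no call. Without untreated tumour 1 they were 0.08 for endothelial genes, 0.17 for keratinocytes and 0.38 for adipocytes. The erythroid and platelet median was 0.67 without untreated tumour 3 and 0.00 without vorinostat tumour 2, also with no call.

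The response lists tied to the drug class were not higher in treated tumours in edgeR, and on log2(TPM + 1) their medians were 0.26 and 0.29, against 0.26 for all genes. Cell cycle inhibitors and genes known to respond to histone deacetylase inhibitors had 11 of 18 members lower and a median of -0.17 (camera adjusted p 0.00931, and adjusted p = 0.920 with an estimated correlation). Its leading members were Btg2 at 5.03 ± 1.79 against 8.96 ± 2.34 CPM, Klf2 at 9.97 ± 4.64 against 18.5 ± 7.70 CPM, Txnip at 16.7 ± 3.65 against 23.6 ± 3.64 CPM and Btg1 at 37.2 ± 5.68 against 49.3 ± 10 CPM. Immediate early and heat shock genes had 14 of 21 members lower and a median of -0.19 (camera adjusted p 0.00931, and adjusted p = 0.902 with an estimated correlation). The heat shock gene Hspa1b stood at 28.9 ± 8.90 against 58.9 ± 13.2 CPM and passed when adjusted over the list alone (0.0288), while Ier2, Zfp36 and Egr1 had log2 fold changes of -0.48, -0.54 and -0.60. Neither call held without vorinostat tumour 3, at medians of -0.13 and -0.07 (camera adjusted p 0.25 for both). The second was also lost without untreated tumour 1 (-0.11, 0.126). Both were called without untreated tumour 3 and vorinostat tumour 3 together (medians -0.18 for both, camera adjusted p 0.0357 and 0.0027). With the satellite share as a covariate both were called too (-0.09 and -0.12, camera adjusted p 0.0382 and 0.0185). The medians were -0.11 and -0.12 without untreated tumour 2, the first was -0.29 without vorinostat tumour 1 and the second -0.32 without untreated tumour 3. Targets of p53 had a median of -0.03 (camera adjusted p 0.217). With 1 tumour left out it ran from -0.17 without vorinostat tumour 3 to -0.05 without untreated tumour 3. In this list 3 members passed when adjusted over the list alone. These were Zmat3 at 30.3 ± 3.94 against 49.1 ± 9.46 CPM, Ccng1 at 40.4 ± 0.367 against 57.8 ± 8.31 CPM and Trp53inp1 at 6.43 ± 1.40 against 10.2 ± 0.887 CPM.

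Genes of the melanocyte lineage and of proliferation did not pass as lists. The median was -0.05 for 20 melanocyte and pigment genes (camera adjusted p 0.204; Erbb3 -0.39, SE 0.16) and 0.09 for 16 genes of dedifferentiation and mesenchymal state (0.826; Tgfbi -0.78, SE 0.39). It was 0.14 for 30 proliferation genes, 22 of them higher (camera adjusted p 0.175; Mcm6 0.43, SE 0.20). Among chromatin genes the medians were -0.01 for deacetylases and acetyltransferases (0.663; Kat6a -0.37, SE 0.22), 0.01 for DNA methylation and Polycomb (0.663; Dnmt3a -0.58, SE 0.22) and 0.06 for replication-dependent histones (0.663; Hist2h3b -0.44, SE 0.24). In these 3 lists and in the NK cell list, the median, the mean and the direction of the test did not all have the same sign. The remaining medians were 0.13 for hypoxia and glycolysis (camera adjusted p 0.663; Adm 0.51, SE 0.17), -0.05 for the unfolded protein and integrated stress response (0.0579; Creld2 -0.55, SE 0.19), -0.05 for cholesterol synthesis (0.117) and -0.24 for mitochondrially encoded genes (0.269; mt-Rnr2 -1.87, SE 1.09, and 0.13 without untreated tumour 3). Leaving out 1 tumour gave some of these lists a camera call. Melanocyte genes were lower without untreated tumour 3 (-0.17), vorinostat tumour 1 (-0.11) or vorinostat tumour 2 (-0.10), and cholesterol genes without untreated tumour 3 (-0.19) or vorinostat tumour 2 (-0.10). Stress response genes were lower without vorinostat tumour 1 (-0.14) or 2 (-0.15), or with members shared between lists left out (-0.10), and proliferation genes were higher without vorinostat tumour 3 (0.20). Replication histones were lower without vorinostat tumour 2 (-0.10) and higher without vorinostat tumour 3 (0.25). Mitochondrially encoded genes were lower without untreated tumour 2 (-0.64) or vorinostat tumour 3 (-0.58) and higher without untreated tumour 3 (0.53). Medians turned with no call without vorinostat tumour 3 for melanocyte (0.07), dedifferentiation (-0.14) and stress response (0.06) genes, and without vorinostat tumour 2 for mitochondrially encoded genes (0.13). They turned for melanocyte genes without untreated tumour 2 (0.02), dedifferentiation genes without untreated tumour 1 (-0.03), proliferation genes without untreated tumour 3 (-0.01), and replication histones without untreated tumour 1 (-0.03) or vorinostat tumour 1 (-0.04). The hypoxia median was 0.02 without untreated tumour 3 and 0.02 without vorinostat tumour 1. The medians of the deacetylase and DNA methylation lists, near 0, turned with some tumours left out as well.

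The other 4 lists had fewer than 5 tested members and were not tested. Of the mast cell list 2 members were tested, Hpgds at 19.0 ± 2.30 against 17.2 ± 4.20 CPM and Gata2 at a log2 fold change of 0.06 (SE 0.41). Of the skeletal muscle list 4 were tested, led by Ryr1 at 1.93 ± 1.12 against 0.997 ± 0.441 CPM. Of 20 germline genes 0 had enough reads. Of the Xist and Y-linked list, Xist stood at 17.6 ± 3.03 against 32.9 ± 22.2 CPM (log2 fold change -0.89, SE 0.42, edgeR adjusted p 0.743), and 4 Y-linked genes had 1 read in all 6 libraries together.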

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

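The tests on protein-coding genes alone, with the satellite share, without 2 libraries, without satellite genes and with a subtracted background were chosen only after the result was seen. The edgeR count of 0 genes stayed at 0 with other scalings, a stricter filter, robust dispersions, a length offset, a minimum fold of 1.5, mitochondrial and ribosomal RNA left out, limma-voom, unfiltered TPM and each of those 5. It was 156 (49 higher, 107 lower) with no filter, 11 (4 higher, 7 lower) with DESeq2, 6 (1 higher, 5 lower) with limma-voom and quality weights, 39 (36 higher, 3 lower) on log2(TPM + 1) and 52 (49 higher, 3 lower) on log2(TPM + 0.1). Leaving out 1 library gave 0 to 121 genes, 0 to 29 higher and 0 to 92 lower, with 121 without untreated tumour 2 and 1 (Ppp1ccb, lower) without untreated tumour 3. Satellite-annotated genes among those called higher numbered 9 with no filter, 13 on each of the filtered TPM scales and 12 without untreated tumour 2. The cause of the differences in count was not tested here, except that 18 of the 156 genes had been removed by the main filter.

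For the 79 genes that the naming rule took, 1680 of 1950 values kept their side of the threshold and lay within 1 SD of the main value, 228 moved by more, 42 passed the threshold in the same direction and 0 passed it in the other. On log2(TPM + 1) the median of all genes lay 0.23 higher than in edgeR and 21 named genes changed sign, 6 of them also relative to that shift; B2m, H2-K1, Cd274, H1f0 and Mitf were among the 21. Of the 6 lower lists, MHC class I, immediate early and inhibitor response had medians of 0.26, 0.29 and 0.26 there, against 0.26 for all genes; relative to all genes none turned on log2(TPM + 0.1).

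The count of 7 lists (1 higher, 6 lower) became 0 (0 higher, 0 lower) with an estimated correlation and with fry, 8 with shared members left out (stress response added, -0.10), and 5 to 13 (1 to 4 higher, 4 to 12 lower) with 1 library left out. The satellite share as a covariate gave 13 lists, 9 higher, among them T cells (0.48), NK cells (0.71, from a median of -0.22) and adipocytes (0.55). It turned the direction of the test, with a call before or after, for MHC class I (median 0.16), the interferon gamma response (0.32), macrophages (0.52), replication histones (0.14), chemokines (0.40), complement (0.36) and mitochondrially encoded genes (0.84). With no call before or after, medians turned for neutrophils (0.68), B cells (0.58), regulatory T cells (0.47) and dendritic cells (0.41), among others, and MHC class II lost its call (0.02). Without untreated tumour 3 and vorinostat tumour 3, 4 lists were higher and 3 lower, and the test turned for macrophages (0.41), replication histones (0.28) and complement (0.26). With 1 library left out, medians ran from -0.38 to 0.32 for macrophages, from -0.64 to 0.53 for mitochondrially encoded genes and from -0.10 to 0.25 for replication histones. The test turned to a call without untreated tumour 3 for the first 2 and without vorinostat tumour 3 for the histones, whose median was positive (0.06) from the start. Smaller groups are part of these fits; the cause was not tested further. No paired analysis was possible because the labels give no replicate numbers that tie treated to untreated tumours.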

Other observations

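Tests on the S numbers, on a wrong label and on treatment and the satellite share were chosen only after the result was seen. So were those on host leukocytes and on Xist, and the genes named here outside the rule. Some genes of heme, iron and glutathione handling were looked at after Hmox1 was seen. Tfrc, the transferrin receptor that brings iron into cells, stood at 96.1 ± 8.74 CPM in treated against 156 ± 5.61 CPM in untreated tumours (log2 fold change -0.70, SE 0.16, edgeR adjusted p 0.743), and DESeq2 called it. Osgin1, Gclm and Gsta4, targets of the oxidative stress factor NRF2, had log2 fold changes of 0.97 (SE 0.25), 0.67 (SE 0.19) and 0.93 (SE 0.23). Lower transferrin receptor with higher heme oxygenase is the pattern of cells with more heme or iron. Of 10 iron and heme genes whose values had not been seen when this test was set, 8 lay in the direction set for them under iron loading. Among these was the iron exporter gene Slc40a1 at 1.03 (SE 0.51), while Slc39a14, which had been set to fall, stood at 0.40 (SE 0.13). The camera test on ranked statistics gave this list a p of 0.0746. Both the count and this p rest on the directions assigned. Of 26 further NRF2 targets 15 were higher at a median of 0.11, with a camera p of 0.282 and of 0.690 with an estimated correlation. A response to heme or iron, or to oxidative stress, therefore may accompany Hmox1, and these tests neither show nor exclude it. A p over 0.05, set beforehand as evidence against it, was too strict a rule, since such a p does not show that values did not differ.

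Xist, the RNA that coats the inactive X chromosome of female cells, followed Ptprc across the 6 tumours. Their order was the same in all 6 (Spearman rho = 1, exact permutation p = 0.00278, the smallest that a two-sided rank test of 6 samples allows, adjusted to 0.00556 over 2 relations), and Pearson's r was 0.998 (exact permutation p = 0.00139). Without the 2 tumours farthest from the median of Ptprc, untreated tumours 1 and 3, r was 0.986. The remaining 4 are also the ones with S numbers 57 to 60, too few to test the relation within either set. Xist ran from 10.8 CPM in untreated tumour 2 to 55.2 CPM in untreated tumour 3, and Ptprc from 6.69 to 28.3 CPM in the same tumours. The 4 Y-linked genes had 1 read in total. A candidate explanation is that Xist reads come from host cells of female mice; rho = 1 is consistent with it, and Xist may then serve as a gauge of the host cells left in these pellets.

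The MHC class II list was lower in treated tumours with the preset correlation (camera adjusted p 0.000564) but was not called with an estimated one (camera adjusted p 0.902). A lower share of host leukocytes is a candidate explanation, with Ptprc at a log2 fold change of -0.78 (SE 0.39, edgeR adjusted p 0.743). A lower share alone would lower all leukocyte genes alike, yet the MHC class II score (mean log2 CPM) shifted against the macrophage score by -0.53 (SD between tumours 0.289, exact permutation p = 0.1, the smallest possible) and against the T cell score by -0.72 (SD 0.419, exact permutation p = 0.2). With 1 tumour left out the first value ran from -0.65 to -0.29, the latter without vorinostat tumour 2, and the second from -0.95 without untreated tumour 1 to -0.44 without untreated tumour 3. The call rested on untreated tumour 3 (median -0.24 without it) and was lost with the satellite share as a covariate (0.02). The macrophage and T cell values do not decide on a share lowered alike for all leukocytes. Their exact permutation p were 0.1 and 0.2, and without vorinostat tumour 2 the first shift was about its SD. The T cell score also lay near 1 CPM (mean log2 CPM 0.25 treated, 0.11 untreated). Xist (-0.89) and the neutrophil (-0.53) and B cell (-0.41) medians go with a lower share of some host cells. Both medians were positive without untreated tumour 3, however. The T cell (0.13), endothelial (0.25) and adipocyte (0.66) medians went the other way. A lower share of some host cells stays open, as do lower MHC class II within leukocytes and the drug itself.

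Without untreated tumour 2, edgeR called 121 genes, among them 15 small nuclear or nucleolar RNAs and the protein-coding genes Luc7l3 (-2.37, SE 0.28), Srek1 (-2.28, SE 0.28) and Rbm25 (-2.02, SE 0.27), all lower in treated tumours. Of the 29 called higher in treated tumours, 12 were satellite-annotated. Setting untreated tumours 1 and 3, the libraries with S numbers 62 and 63, against the other 4 libraries called 204 genes, while the other 14 splits of 2 from 4 called at most 1. The 204 held 111 of the 121 genes, and 12 satellite-annotated genes lower in untreated tumours 1 and 3. Among the 204 were also Ptprc, Xist and members of called lists: H2-Aa, H2-Eb1, H2-Ab1, Rsad2, Col3a1, Hspa1b, Zfp36 and Eno2. Untreated tumours 1 and 3 also had the lowest satellite shares, at 0.337% and 0.174%, and the highest Ptprc, at 18.2 and 28.3 CPM. The 204 genes mark a structure of the samples. It may follow whatever the S numbers stand for, the satellite share or the share of host cells, which were not told apart. A wrong label on untreated tumour 2 cannot be told apart from it either. The mean correlation of that tumour with treated tumours exceeded that with untreated ones by 0.0104, and the ranges overlapped (0.945 to 0.972 against 0.941 to 0.964). Subtracting an even genomic background left 56 of the 121 calls, but the 65 that ended kept a median absolute log2 fold change of 1.41 (SE 0.29 before, 0.30 after), so they ended at the threshold and not through a smaller fold. An effect of vorinostat on these genes, with untreated tumour 2 unlike its group, stays open and untested.

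Satellite-annotated genes took between 0.174% and 22% of reads. The neuronal list was higher in treated tumours with the preset correlation but was not called with an estimated one (camera adjusted p 0.902). Its score was highest in vorinostat tumour 3 (2.23) but higher in untreated tumour 2 (1.57) than in vorinostat tumours 1 and 2 (1.31 and 1.18). Genomic DNA in the libraries may account for the satellite reads, as reads in 1336 chemoreceptor genes, silent in most tissues, ran with their share. Spearman rho was 0.829 (exact permutation p = 0.0583, also after adjustment over 2 relations), short of the threshold in rank. Pearson r was 0.931 (exact permutation p = 0.0250). It was 0.906 without vorinostat tumour 3 and untreated tumour 2, the libraries farthest from the median satellite share. Untreated tumour 2 went against the relation, with 58.5 RPM at a satellite share of 9.83%, where vorinostat tumour 1 had 65.0 RPM at 1.63%. Both measures are shares of the same assigned reads, so mitochondrial ribosomal RNA in untreated tumour 3 lowers both together. On libraries scaled with TMM factors, untreated tumour 3 lay above vorinostat tumours 1 and 2 in chemoreceptor reads. The relation was not tested on that scale, so it does not decide on genomic DNA. Transcription of satellites under vorinostat, a drug that opens chromatin, could not be separated from genomic DNA. The satellite share overlapped between the groups (exact permutation p = 0.5), with 9.83% in untreated tumour 2. Chemoreceptor reads per assigned read did not overlap (25.3 to 58.5 RPM untreated, 65.0 to 167 RPM treated), but they did on libraries scaled with TMM factors. For the neuronal list, subtracting a background even over gene length gave a median of 0.91 over the 8 members still tested (camera adjusted p 0.00107), where the same 8 had 0.91 before. That would argue against genomic DNA, but an even profile is an assumption that the satellite share itself does not meet, and with that share as a covariate the call was lost (median 0.30, adjusted p 0.128), so it stays open.

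With 3 tumours in each group there are 10 splits, too few for a share under 0.05. For genes the real split gave 0 calls and the highest of the others 1. For lists the real split gave 7 calls and the highest of the others 20, and all 10 splits gave at least as many as the real one. Splits that call several times the real count of lists point to a structure of the samples. A preset correlation of 0.01 that is too low for these lists would give such counts too, as the estimated correlations of the 7 called lists ran from 0.134 to 0.606; the 2 were not told apart.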
